A study of Mus musculus with 8 samples.

How the data were processed

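Liver RNA was measured by sequencing in 8 mouse libraries, which the labels put in 4 groups of 2. The Yap control group held Yap1 floxed livers given an AAV8 virus carrying GFP, and the Yap1 knockout group held livers given AAV8-iCre, which deletes Yap1 in hepatocytes. The Ctgf control group held Ctgf floxed livers and the Ctgf knockout group Ctgf conditional knockout livers. The Cre driver of the Ctgf knockout is not given in the sources used here. Per the labels' protocols, RNA was taken from frozen liver with Trizol. The protocol names an Illumina TruSeq kit and a KAPA mRNA HyperPrep kit, and which library was made with which kit is not given in the sources used here. The age of the mice is 8 to 10 weeks in the sample labels and 8 weeks in the design text.

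The authors deposited a table of whole-number read counts, with a line for each gene symbol and a column for each library. Per the submitters' processing notes, bcl2fastq 2.20.0.422, STAR 2.6.0a and HTSeq 0.6.1 were used, and the builds named are mm10 and GRCm38, which are the same assembly. The gene annotation, the strand setting of the counting and any read filter are not given in the sources used here. Counts of antisense and overlapping genes are therefore uncertain, because reads of a gene and its partner may not have been told apart. Counts in families of near-identical genes (Akr1c, Cyp2c, Mup, Amy, Try, Serpina3 and Hbb) are uncertain too, since their reads could be split or dropped. The table held 22155 genes, of which 4534 had no count in any library, and the number of its columns not used was 0. Gene positions were taken from the GENCODE annotation of GRCm38 by gene symbol, and 21682 symbols matched. A symbol that did not match, Ctgf among them, has no position here.

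The total count per library ran from 26904021 to 33488609. A count of 3, used as the floor for a gene listed at 0, corresponded to 0.083 to 0.123 CPM, the usual unit of counts scaled to library size. The reads carry no molecular identifiers, so intervals and floors cover counting error only. Shares of counts have 95% Wilson intervals. The labels do not say that replicates came from separate animals, so the p-values measure the spread between these samples, which may be technical.

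Genes were tested with edgeR's quasi-likelihood F test (edgeR 4.0.16 in R 4.3.3) on the deposited counts, with TMM scaling and edgeR's own low-count filter, which left 13999 genes. All 8 libraries entered a single fit of the 4 groups, which left 4 residual degrees of freedom, and the biological coefficient of variation was 27.2%. The spread of each gene was shared by all 4 groups, which assumes that they vary alike. The comparisons were Yap1 knockout against Yap control, Ctgf knockout against Ctgf control, and the difference between these effects. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and adjusted p under 0.05 was the threshold. Log2 fold changes are knockout over control and are given with their standard error (SE), taken from the fold change and the F statistic. Levels are given in CPM of the TMM-scaled library as mean ± SD with n = 2 libraries per group.

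In all, 49 gene lists (pathways, cell types and stress responses, 1016 genes, 1007 of them in the table) were written down, and the 46 with at least 5 tested genes were tested. The test was limma's camera (limma 3.58.1) with a preset correlation of 0.01 between genes, adjusted over the 46 lists, which asks whether a list moved more than other genes. It was run again with the correlation estimated from the data, and with limma's fry, which asks whether the genes of a list move, on balance, 1 way. For each list the genes past the threshold were also counted after adjustment over the list alone. In every list past the camera test, the median, the mean and the test had the same sign.

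The groups, the tests, the lists, the alternative settings and the rule for genes to name were fixed before the data were examined. The rule named 14 genes always. It added, per knockout comparison, up to 8 genes per direction with the largest change past the threshold, with both knockout libraries on the same side of both controls and at least 5 CPM in a group. Predicted genes, immunoglobulin and T cell receptor segments and Mup genes were left out. Where fewer than 4 genes passed in a direction, those with the smallest p filled up to 4, as values that did not pass. For each list past the test it named the 3 members with the smallest p in the direction of the list, and for the difference between the effects up to 5 genes per direction past the threshold. This gave 87 genes for the Yap1 comparison and 75 for the Ctgf comparison, and genes named outside the rule are said to be so.

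The alternative settings were size factors by RLE or the upper quartile, DESeq2 1.42.0, limma-voom, no low-count filter, a stricter filter of 1 CPM in 2 libraries, only the libraries of the comparison, the replicate number as a block, a robust spread, a minimum change of 2-fold, and each library left out in turn. A fit without both Yap control replicate 2 and the library labelled Ctgf knockout replicate 2 was added after seeing the data. The fits were tested on simulated data drawn from the real means, spreads and library sizes of the 13999 genes, with changed genes, raised or lowered, picked among those above a minimum mean level. Apart from the changes set, each simulated gene had a single mean and a single spread in all 8 libraries. In the Yap1 comparison 89% of the 100 genes changed 4-fold and 9% of the 100 changed 2-fold were recovered, with 4 false calls among 102. In the Ctgf comparison these shares were 87% and 3%, with 5 false calls among 95. Figures were drawn with matplotlib 3.10.9.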

Results

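Transcript levels were measured in mouse liver recovering from a combined injury, to ask what hepatocyte Yap1 and Ctgf contribute to them. Yap1 encodes a transcriptional coactivator that the Hippo pathway restrains, and Ctgf encodes a secreted matrix-associated protein of the CCN family that YAP is known to induce. Adult mice, C57BL/6 by label, drank a Lieber-DeCarli liquid diet with ethanol at 1% over 2 days and at 2% over the next 10 days. They received carbon tetrachloride (CCl4), a hepatotoxin that injures pericentral hepatocytes, at 1 µl per g of body weight 2 days before the liver was taken. The deposited read counts covered 8 libraries. Total counts were 30966991 and 26904021 in Yap controls 1 and 2, 31054353 and 30183302 in Yap1 knockouts 1 and 2, 30956221 and 33366699 in Ctgf controls 1 and 2, and 28478796 and 33488609 in the libraries labelled Ctgf knockout 1 and 2.

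The libraries of the Yap and the Ctgf lines lay apart on the first principal component, which held 49.2% of the variance. Yap control replicate 2 lay apart on the second (22.1% of the variance), at -82.0, where the other libraries ranged from -10.4 to 26. That library also held transcripts of digestive enzymes of the pancreas, such as Ctrb1 at 5454 CPM and Prss2 at 1839 CPM. The exocrine pancreas genes took 1.51% of its counts (95% Wilson interval 1.506% to 1.515%), against 0.00033% to 0.0008% in the others. The Pearson correlation of log CPM between replicates was 0.933 in the Yap controls, 0.984 in the Yap1 knockouts, 0.993 in the Ctgf controls and 0.971 in the libraries labelled Ctgf knockout.

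**Figure D1:**
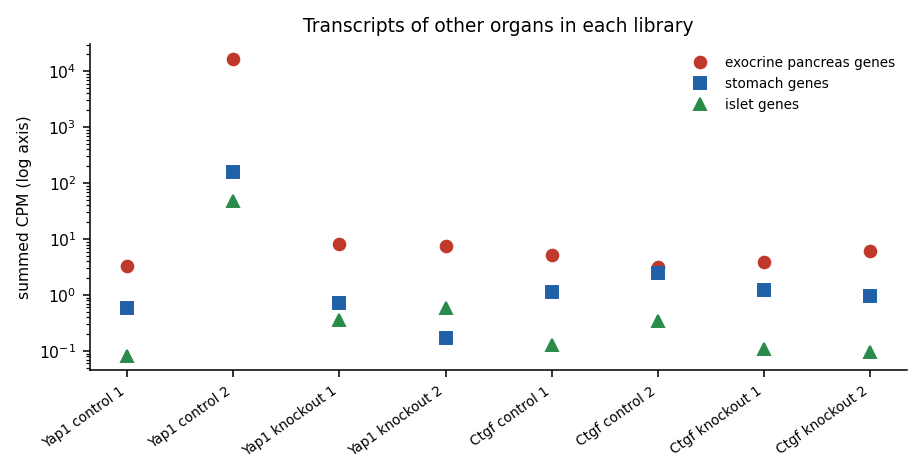
Summed CPM of exocrine pancreas, stomach and islet genes (log axis) in each of the 8 libraries, 1 point per library and list, with a sum under the level of 3 counts drawn at that level. Yap control replicate 2 held 16731 CPM of exocrine pancreas genes, and the other libraries held 3.13 to 8.20.

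Yap1 itself (GRCm38 chromosome 9, 7931999 to 8004596, minus strand) stood at 31.0 and 32.5 CPM in the Yap1 knockouts and at 107 and 76.2 CPM in the Yap controls. The log2 fold change was -1.53 (SE 0.215, n = 2 against 2), so knockout liver held 2.88-fold less, with transcript of all liver cells in the measure. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the adjusted p was 0.0557, just outside the threshold. It was 6.01e-08 with DESeq2 and 0.0458 without a low-count filter. Without Yap control replicate 1 it was 0.00638 and without replicate 2 0.0345. It was 0.507 and 0.619 without Yap1 knockout replicate 1 and 2, 0.264 without either Ctgf control, 0.113 and 0.12 without either library labelled Ctgf knockout, and 0.329 in a fit of the Yap libraries alone. In the Ctgf line Yap1 stood at 139.5 and 132 CPM in the controls and at 139 and 136 CPM in the libraries labelled knockout.

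Ctgf stood at 28.8 and 32.1 CPM in the Ctgf controls and at 8.02 CPM in Ctgf knockout replicate 1. In the library labelled Ctgf knockout replicate 2 it stood at 49.2 CPM, above both controls, which goes against that label. The log2 fold change over both libraries was -0.09 (SE 0.69, edgeR adjusted p = 1). Without the library labelled Ctgf knockout replicate 2 it was -1.92, and without replicate 1 it was 0.71 (adjusted p = 1 for each). The related CCN gene Cyr61 did not part the labelled knockouts in this way, at 39.9 and 42.4 CPM against 80.7 and 91.1 CPM in the controls (log2 fold change -1.06, SE 0.327, adjusted p = 1).

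**Figure D2:**
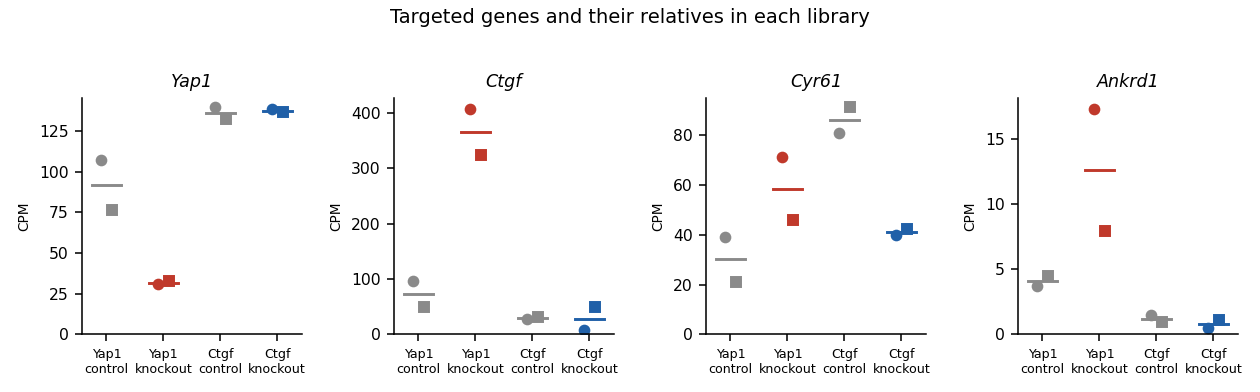
CPM of Yap1, Ctgf, Cyr61 and Ankrd1 in each library (circles, replicate 1; squares, replicate 2), with a line at the mean of each group of 2. Yap1 stands at 31.0 and 32.5 CPM in the Yap1 knockouts, and Ctgf stands at 49.2 CPM in the library labelled Ctgf knockout replicate 2, above its controls.

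The first comparison asked how hepatocyte Yap1 deletion altered the injured liver. Adm, which encodes the vasodilator peptide adrenomedullin and is induced by low oxygen, rose 9.65-fold, from 5.38 ± 0.253 to 51.9 ± 7.28 CPM (SD, n = 2). Cd28, a co-stimulatory receptor of T cells, rose 31.7-fold, from 0.674 ± 0.211 to 21.2 ± 6.10 CPM. Ndufa4l2, a hypoxia-induced mitochondrial protein, rose 9.98-fold, from 1.16 ± 0.123 to 11.6 ± 0.65 CPM. Akr1c20, a hepatic aldo-keto reductase of steroid metabolism whose near-identical relatives make its count uncertain, decreased from 21.5 ± 1.37 to 1.81 ± 0.461 CPM, an 11.8-fold drop. These were the genes past the threshold, 3 higher and 1 lower among 13999 tested by edgeR's quasi-likelihood test, with log2 fold changes of 3.27 (SE 0.238) for Adm, 4.99 (SE 0.382) for Cd28, 3.32 (SE 0.319) for Ndufa4l2 and -3.56 (SE 0.278) for Akr1c20. The adjusted p was 0.0249 for Ndufa4l2 and 0.00699 for the others.

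Adm lies on chromosome 7 (110627661 to 110629820, plus strand), Cd28 on chromosome 1 (60716800 to 60773359, plus strand), Ndufa4l2 on chromosome 10 (127514967 to 127517154, plus strand) and Akr1c20 on chromosome 13 (4486849 to 4523345, minus strand) of GRCm38. Just outside the threshold stood Tgm2, which encodes the cross-linking enzyme transglutaminase 2, at 2047 ± 94.2 against 462 ± 46.7 CPM (log2 fold change 2.15, SE 0.236, edgeR adjusted p = 0.0521). The progestin receptor gene Paqr7 stood at 10.7 ± 1.81 against 42.8 ± 8.89 CPM, and Ppp1r3c, a glycogen-targeting phosphatase subunit, and Rtp3 had log2 fold changes of -2.27 and -1.88 (adjusted p = 0.0557 for each). At an unadjusted p under 0.05 there were 929 genes higher and 999 lower, 1928 in all against 699.95 by chance. Other splits of the same Yap libraries into pairs, each mixing knockout and control, gave 1034 and 272 such genes. An excess over the chance number therefore does not by itself show an effect of Yap1 deletion. DESeq2 called 277 higher and 281 lower, limma-voom called Tgm2 and the same 4 genes, and edgeR without a low-count filter called 24 higher and 13 lower. The number of calls was 0 in a fit of the Yap libraries alone, with 1238 genes at an unadjusted p under 0.05.

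Without Yap control replicate 1 the knockouts were set against a single control, Yap control replicate 2, the library with pancreatic transcripts. The log2 fold changes of Adm, Cd28, Ndufa4l2 and Akr1c20 were then 3.19, 4.65, 3.41 and -3.65. Against Yap control replicate 1 alone these 4 genes had 3.32, 5.32, 3.22 and -3.49. No gene passed without Yap1 knockout replicate 1 or 2, when the adjusted p of Cd28 was 0.137 and 0.138 and that of Adm 0.137 and 0.174. The log2 fold changes were then 4.66 and 5.25 for Cd28 and 3.41 and 3.12 for Adm. No gene passed without Ctgf knockout replicate 1 or the library labelled Ctgf knockout replicate 2 either, with adjusted p of 0.0728 and 0.0759 for Adm. Without Ctgf control replicate 1 or 2 Ndufa4l2 did not pass (adjusted p = 0.143 and 0.141). Without both Yap control replicate 2 and the library labelled Ctgf knockout replicate 2, a setting chosen after seeing the data, 530 genes were higher and 408 lower, these 4 among them.

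**Figure D3:**
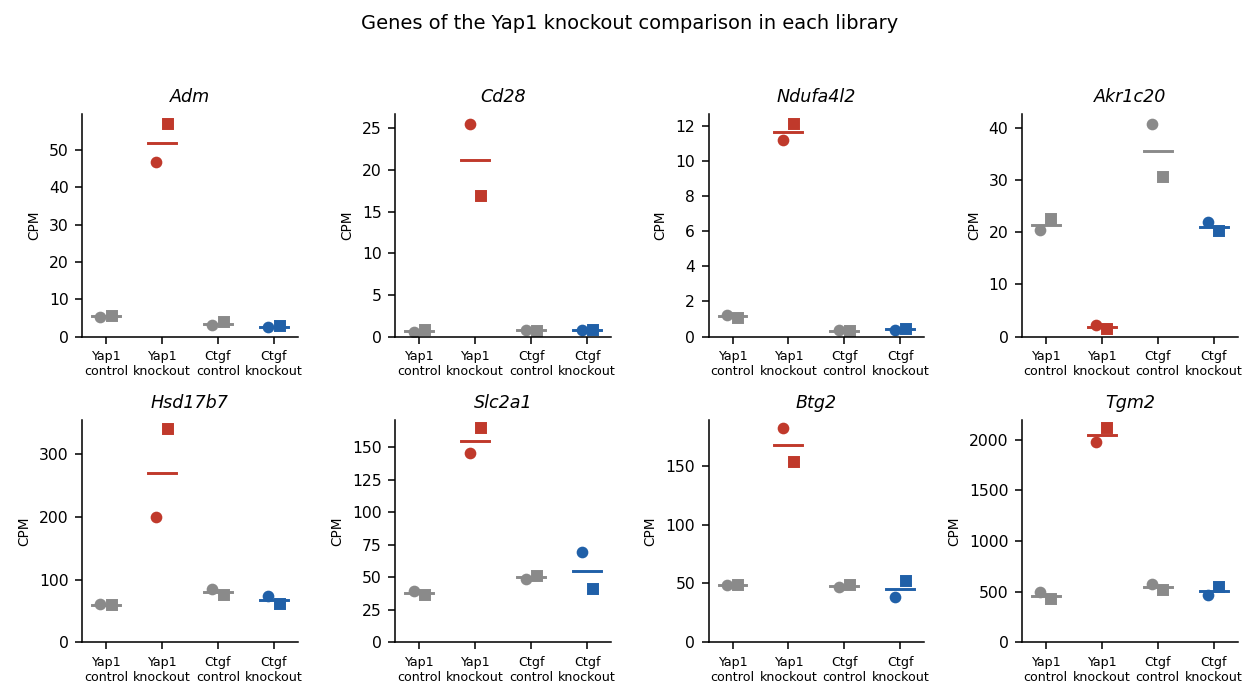
CPM of 8 genes in each library (circles, replicate 1; squares, replicate 2), with a line at the mean of each group of 2. Adm, Cd28, Ndufa4l2 and Akr1c20 passed the edgeR test in the Yap1 comparison; Hsd17b7, Slc2a1, Btg2 and Tgm2 are shown as values, with both Yap1 knockouts above every other library.

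Among the preset gene lists, genes of cholesterol synthesis rose in Yap1 knockout liver, with a median log2 fold change of 1.32 and 23 of 25 members above 0. No member passed over all genes, and 18 were higher when adjusted over the list alone (camera adjusted p = 9.82e-26, adjusted p = 0.406 with an estimated correlation). Hsd17b7, a reductase of the pathway, had a log2 fold change of 2.17 (SE 0.281) and Idi1, the isopentenyl diphosphate isomerase, 2.66 (SE 0.371), with an edgeR adjusted p of 0.0557 for each. Genes of glycolysis and hypoxia rose as well, with a median of 0.90, and 1 of 21 (Adm) passed over all genes and 14 when adjusted over the list alone (camera adjusted p = 1.18e-17, adjusted p = 0.331 with an estimated correlation). In that list the glucose transporter Slc2a1 stood at 155 ± 13.5 against 37.8 ± 2.06 CPM, and the oxygen-sensing hydroxylase Egln3 at 54.4 ± 12.0 against 16.3 ± 1.19 CPM (adjusted p = 0.0557 and 0.0959).

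Neutrophil markers rose, with a median of 1.80 over 20 genes, and 13 were higher when adjusted over the list alone and 0 over all genes (camera adjusted p = 1.28e-10, adjusted p = 0.406 with an estimated correlation). Erythroid genes, a sign of blood in the tissue, rose in the same libraries (median 1.21, camera adjusted p = 8.87e-04, adjusted p = 0.568 with an estimated correlation), with the globin gene Hbb-bs at 266 ± 30 against 98.9 ± 38.5 CPM. Retnlg, a neutrophil resistin-like protein, stood at 94.7 ± 44.7 against 12.7 ± 7.11 CPM, and the log2 fold changes of the neutrophil collagenase Mmp8 and the decoy receptor Il1r2 were 2.47 and 2.17 (adjusted p = 0.091, 0.159 and 0.157). Immediate early genes rose with a median of 0.69, 3 of 20 when adjusted over the list alone (Btg2, Ier3 and Dusp1; camera adjusted p = 1.97e-06, adjusted p = 0.356 with an estimated correlation). Growth factors and receptors of regeneration rose with a median of 0.58, 3 of 24 when adjusted over the list alone (Vegfa, Hbegf and Fgfr1; camera adjusted p = 7.53e-04, adjusted p = 0.479 with an estimated correlation). With each of the 8 libraries left out in turn, the medians were 0.96 to 1.88 for cholesterol synthesis, 0.88 to 1.12 for glycolysis and hypoxia, 1.21 to 2.48 for neutrophil markers, 0.56 to 0.71 for immediate early genes and 0.45 to 0.79 for growth factors. These 5 lists passed the camera test each time, and the erythroid list did not without Yap control replicate 1 (camera adjusted p = 0.256).

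Several lists of matrix and signalling genes passed the camera test with few members past it singly, and lost the call without Yap control replicate 2. The fibrosis and activated stellate cell list had a median of 0.21, and over the list alone Lox and Fn1 were higher and Eln and Lum lower (camera adjusted p = 0.00641, adjusted p = 0.645 with an estimated correlation; 0.424 without that library). Acta2, the actin of activated stellate cells, stood at 124 ± 1.79 against 73.5 ± 2.08 CPM, and Col1a1 at 170.3 ± 33.3 against 173 ± 35.6 CPM (adjusted p = 0.263 and 0.977). The TGF-beta response had a median of 0.38, with 3 of 18 members higher over the list alone (camera adjusted p = 0.00641, adjusted p = 0.645 with an estimated correlation; 0.424 without that library). Of these, Tgif1, a corepressor induced by TGF-beta, had a log2 fold change of 0.99 (SE 0.176, adjusted p = 0.105) and Bhlhe40 1.42 (SE 0.36, adjusted p = 0.19). The integrin and adhesion list had a median of 0.56 with 0 genes over the list alone (camera adjusted p = 0.00641, adjusted p = 0.568 with an estimated correlation; 0.102 without that library and 0.0511 without Yap1 knockout replicate 1). Leaving out Yap control replicate 1 gave medians of 0.74 for fibrosis, 0.61 for the TGF-beta response and 0.86 for integrins. The only control was then Yap control replicate 2, the library with pancreatic transcripts.

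The YAP/TAZ target signature had a median of 0.30, with 16 of 21 members above 0, so it moved upward in livers without hepatocyte Yap1 (camera adjusted p = 0.00905, adjusted p = 0.645 with an estimated correlation). Over the list alone Nt5e and F3 were higher and Ajuba lower. The classical targets Ctgf, Ankrd1 and Cyr61 had log2 fold changes of 2.31 (SE 0.718), 1.61 (SE 0.497) and 0.96 (SE 0.327), with edgeR adjusted p of 0.25, 0.25 and 0.283. Ctgf stood at 406 and 324 CPM in the knockouts and at 96.8 and 50.1 CPM in the controls. The call on the list was lost without Yap control replicate 2 and without Yap1 knockout replicate 1. The median was 0.70 without Yap control replicate 1, when the library with pancreatic transcripts was the only control.

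The erythroid list, named above beside the neutrophil markers, acute phase proteins (median 0.40) and mitochondrially encoded genes (0.50) rose, and 4, 2 and 1 members were higher over the list alone (camera adjusted p = 8.87e-04, 0.00187 and 0.0161; adjusted p = 0.568, 0.645 and 0.568 with an estimated correlation). Without Yap control replicate 1 the camera adjusted p of these lists was 0.256, 0.957 and 0.0915, the acute phase median turning to -0.12, and for acute phase proteins it was 0.0618 without Yap1 knockout replicate 1. For the mitochondrial list it was 0.0513 without both Yap control replicate 2 and the library labelled Ctgf knockout replicate 2. Serpina3m and Serpina3n, acute phase protease inhibitors with near-identical relatives, had log2 fold changes of 1.60 and 1.51 (adjusted p = 0.167 and 0.215). Mitochondrial transcripts took 3.76% and 4.58% of the counts in the Yap1 knockouts and 3.50% and 2.12% in the controls.

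Of the lists that fell in Yap1 knockout liver, pericentral hepatocyte genes had the lowest median, -1.12, with 5 of 25 lower when adjusted over the list alone (camera adjusted p = 3.25e-06, adjusted p = 0.568 with an estimated correlation). The R-spondin receptor Lgr5 stood at 0.416 ± 0.343 against 4.11 ± 2.40 CPM and the retinal dehydrogenase Aldh1a1 at 61.2 ± 13.3 against 202 ± 86.2 CPM (adjusted p = 0.163 and 0.12). Genes of PPAR-alpha and fatty acid oxidation had a median of -0.78, with Acot1 and Acaa1b lower over the list alone (camera adjusted p = 5.12e-06, adjusted p = 0.645 with an estimated correlation). Both calls rested on Yap control replicate 2, the library with pancreatic transcripts, since without it the medians were -0.03 and -0.01. The Yap controls themselves differed in such genes, with Acaa1b at 85.2 and 379 CPM and Aldh1a1 at 141 and 263 CPM in replicates 1 and 2. The pericentral gene Rnf43 went the other way, at 20.7 and 15.6 CPM. Whether the pancreatic tissue bears on this difference was not tested.

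The same held for 4 lists of hepatocyte metabolism and translation. Xenobiotic metabolism (median -0.74) and cytosolic ribosomal proteins (-0.36) passed the camera test, with 0 members over the list alone (camera adjusted p = 0.016 and 0.00905; adjusted p = 0.718 and 0.766 with an estimated correlation). Without Yap control replicate 2 their medians were 0.52 and 0.14 (camera adjusted p = 0.279 and 0.265). Bile acid synthesis and transport (median -0.36) and ethanol metabolism (-0.56) also passed, with 2 lower in the first and 4 lower and 1 higher in the second over the list alone (camera adjusted p = 0.02 and 0.0211; adjusted p = 0.645 for each with an estimated correlation). Without that library their medians were 0.13 and -0.17 (camera adjusted p = 0.86 and 0.934), and without Yap1 knockout replicate 1 the xenobiotic, bile acid and ethanol lists gave 0.197, 0.0562 and 0.0962. Ethanol metabolism also stood at 0.0548 without Ctgf knockout replicate 1 and at 0.051 without the library labelled Ctgf knockout replicate 2. Adh1, the main hepatic alcohol dehydrogenase, had a log2 fold change of -1.38 (SE 0.298) and Acss2, which activates acetate, 1.41 (SE 0.282), a gene chosen after its value was seen (adjusted p = 0.148 and 0.126).

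Lists of mitosis, DNA replication, T and NK cell, sinusoidal endothelial and heat shock genes fell too. The Kupffer cell, monocyte-derived macrophage and B and plasma cell lists did not pass (camera adjusted p = 0.347, 0.114 and 0.392). Mitosis genes had a median of -0.63 and DNA replication genes of -0.37, with 29 of 30 and 26 of 30 members below 0 and 0 past the test over the list alone (camera adjusted p = 3.11e-04 and 0.00632; adjusted p = 0.645 and 0.637 with an estimated correlation). T and NK cell markers (median -0.62, 0 over the list alone) fell while Cd28 rose (camera adjusted p = 0.0129, adjusted p = 0.645 with an estimated correlation). Sinusoidal endothelial markers had a median of -0.51, with Clec4g and Bmp2 lower and Lyve1 higher over the list alone, and heat shock proteins a median of -0.54 with 0 (camera adjusted p = 0.00531 for each, adjusted p = 0.645 for each with an estimated correlation). Without Yap control replicate 1 the medians of these 5 lists, in this order, were -0.00214, -0.23, -0.42, -0.14 and -0.30 (camera adjusted p = 0.629, 0.39, 0.37, 0.523 and 0.126). Without Yap1 knockout replicate 1 mitosis and DNA replication gave 0.122 and 0.068, and without replicate 2 T and NK markers gave 0.0688.

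In all, 12 lists rose and 11 fell of 46 in the Yap1 comparison. With an estimated correlation 0 lists passed, and fry passed 2, glycolysis and hypoxia and the mitochondrially encoded genes (fry adjusted p = 0.0497). Other splits of the same Yap libraries into pairs gave 22 and 24 lists by camera, against 23 for the real split. The number of lists past camera therefore does not set the knockout apart from other groupings. Markers of bile duct cells did not pass (median -0.19, camera adjusted p = 0.883), and Krt19 and Epcam were high in Yap control replicate 2 alone, with Krt19 at 32.6 CPM there. Hepatocyte core genes did not pass (median -0.18, camera adjusted p = 0.347). Alb, Cyp2e1 and Spp1 had log2 fold changes of -0.25, -0.62 and -0.61, which turned positive without Yap control replicate 2. Sox9, Afp and Mki67 had log2 fold changes of 0.77, 2.06 and -0.51 (adjusted p = 0.198, 0.334 and 0.644), and the sign of Afp turned without Yap1 knockout replicate 2 and that of Mki67 without Yap control replicate 1.

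**Figure D4:**
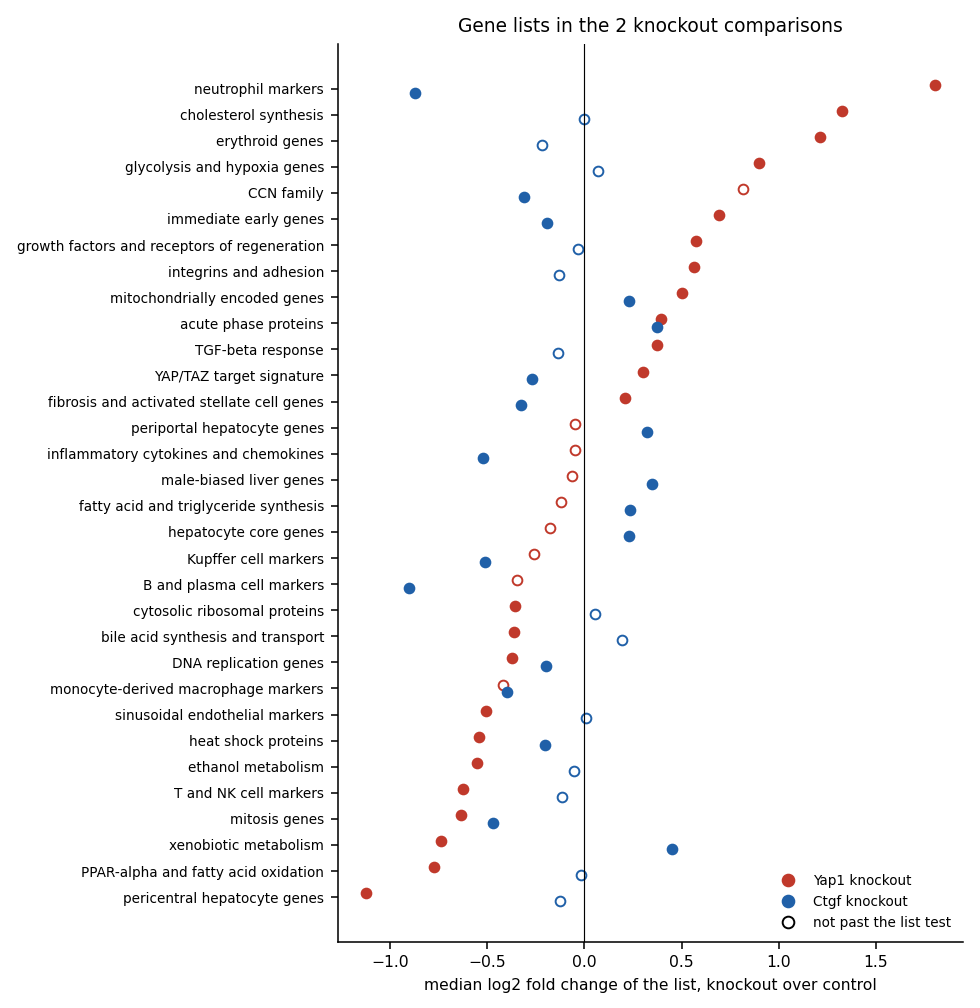
Median log2 fold change (knockout over control) of the preset lists past the camera test with the preset correlation in at least 1 knockout comparison, with filled points past the test and open points not. Neutrophil markers lie at 1.80 in the Yap1 comparison and at -0.87 in the Ctgf comparison, and no filled point passed with an estimated correlation.

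The second comparison asked what Ctgf deletion altered after the same ethanol and CCl4 treatment. Its directions are drawn from Ctgf knockout replicate 1 and the library labelled Ctgf knockout replicate 2, whose Ctgf level goes against the label. Ifi202b, an interferon-inducible gene whose level is known to differ between inbred mouse strains (GRCm38 chromosome 1, 173962568 to 173982744, minus strand), had 235 and 273 counts in the controls (7.63 ± 0.192 CPM, n = 2). It had 0 counts in both libraries labelled knockout, at least 71-fold lower against a floor of 3 counts per library. All libraries of the Yap line together held 1 count of it, so the Ctgf controls alone stood at this level. A difference in background of these controls therefore cannot be told apart from an effect of Ctgf deletion. The edgeR adjusted p of Ifi202b was 0.41, and it was 5.37e-07 with DESeq2 and 0.0127 with limma-voom. Lpin1, a phosphatidate phosphatase of triglyceride synthesis, stood at 119.8 ± 61.3 against 35.3 ± 2.40 CPM (log2 fold change 1.77, SE 0.372), and the stress-induced gene Ddit4 at 20.7 ± 0.555 against 8.87 ± 1.20 CPM. The inflammatory cytokine Tnf stood at 1.47 ± 0.479 against 6.09 ± 0.406 CPM (log2 fold change -2.04, SE 0.453), and Il6 had a log2 fold change of -2.34 (SE 0.909; edgeR adjusted p = 1 for each).

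By edgeR's quasi-likelihood test 0 genes were higher and 0 lower. At an unadjusted p under 0.05 there were 277 genes, 92 higher and 185 lower, against 699.95 by chance. The mean variance of log2 CPM between replicates was 0.0584 in the Ctgf controls and 0.24 in the libraries labelled Ctgf knockout. It was 0.478 in the Yap controls and 0.112 in the Yap1 knockouts. A spread shared by all groups is then too wide for the Ctgf controls and too narrow for the Yap controls. A count under the chance number therefore does not show that Ctgf deletion changed nothing. DESeq2 called 1 gene higher (Lpin1) and 3 lower (Ifi202b, Ndor1 and Ctrb1), where Ctrb1, a pancreas gene at no more than 0.03 CPM in this line, was chosen after its value was seen. Limma-voom called Ifi202b, and a fit of the Ctgf libraries alone called 0 with 521 at an unadjusted p under 0.05. That number was 754 without Ctgf knockout replicate 1 and 586 without the library labelled Ctgf knockout replicate 2, with 0 calls in each. Also without a pass, the log2 fold changes were -1.01 for Ndor1, -1.29 for Rnf39 and 0.85 for Col15a1 (adjusted p = 1 for each). With the simulated data the same design recovered 87% of genes changed 4-fold and 3% of those changed 2-fold. The simulation gave each gene a single spread in all groups, unlike the real groups. These shares therefore do not tell how many real changes of such a size were missed here.

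Among the lists, neutrophil markers fell in the libraries labelled Ctgf knockout, with a median of -0.87 and 18 of 20 members below 0 (camera adjusted p = 1.25e-16, adjusted p = 0.447 with an estimated correlation). Retnlg stood at 3.89 ± 0.0633 against 11.6 ± 2.30 CPM, and the granule genes Ltf and Camp had log2 fold changes of -3.01 and -2.55 (edgeR adjusted p = 1 for each). The fibrosis and activated stellate cell list fell, with a median of -0.33 and 28 of 31 members below 0 (camera adjusted p = 1.21e-07, adjusted p = 0.447 with an estimated correlation). Markers of mesothelial cells, a list added after seeing the data, stood lower in the same libraries, with sums of 9.29 and 6.96 against 24 and 17.9 CPM. Collagens Col1a2 and Col5a2 had log2 fold changes of -0.75 and -1.06, Col1a1 -0.58 and Acta2 -0.40 (adjusted p = 1 for each). Mitosis genes fell with a median of -0.47 and the YAP/TAZ target signature with -0.27 (camera adjusted p = 3.09e-06 and 2.77e-04; adjusted p = 0.633 and 0.575 with an estimated correlation). Ptpn14 and Myof of that signature had log2 fold changes of -1.07 and -0.75 (adjusted p = 1 for each). These 4 lists passed the camera test with each library left out in turn, with medians of -1.35 to -0.55 for neutrophil markers, -0.46 to -0.27 for fibrosis, -0.75 to -0.35 for mitosis and -0.30 to -0.14 for the YAP/TAZ signature. In none of them did a member pass over all genes or when adjusted over the list alone.

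Other immune lists fell with 0 members past the test over all genes or over the list alone. Kupffer cell markers had a median of -0.51, inflammatory cytokines and chemokines -0.52, monocyte-derived macrophage markers -0.40 and B and plasma cell markers -0.91 (camera adjusted p = 2.51e-11, 1.32e-08, 1.21e-05 and 2.68e-04; adjusted p = 0.447, 0.447, 0.628 and 0.575 with an estimated correlation). Csf1r, the receptor macrophages need, stood at 82.4 ± 16.5 against 139 ± 38.2 CPM and the resident macrophage receptor Timd4 at 10.4 ± 4.73 against 21.9 ± 3.44 CPM (edgeR adjusted p = 1 for each). Immediate early genes had a median of -0.19, DNA replication genes -0.20 and the CCN family -0.31 (camera adjusted p = 3.96e-04, 0.0206 and 0.0161; adjusted p = 0.447, 0.628 and 0.447 with an estimated correlation). Without Ctgf knockout replicate 1 these 7 lists gave camera adjusted p of 0.0647, 0.491, 0.182, 0.491, 0.677, 0.605 and 0.179, the macrophage median turning to 0.09. Without Ctgf control replicate 2 B and plasma cell markers and DNA replication genes gave 0.0689 and 0.262, and the CCN family gave 0.0617 without the library labelled Ctgf knockout replicate 2.

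Several lists of hepatocyte genes rose, and these calls rested on the library labelled Ctgf knockout replicate 2, while pericentral hepatocyte genes did not pass (median -0.12, camera adjusted p = 0.132). Hepatocyte core genes had a median of 0.23, xenobiotic metabolism 0.45, periportal genes 0.32 and male-biased liver genes 0.35 (camera adjusted p = 0.00121, 0.00145, 0.00329 and 9.23e-04; adjusted p = 0.783, 0.774, 0.628 and 0.447 with an estimated correlation). Without that library their medians were -0.12, -0.12, -0.16 and -0.02 (camera adjusted p = 0.485, 0.633, 0.633 and 0.623), and male-biased genes gave 0.0693 without Ctgf control replicate 2. Fatty acid and triglyceride synthesis had a median of 0.23, with 1 of 25 (Lpin1) higher over the list alone, and acute phase proteins had 0.37 (camera adjusted p = 6e-06 and 5.1e-06; adjusted p = 0.447 and 0.628 with an estimated correlation). Without that library the camera adjusted p was 0.343 and 0.0547. Fgg and Fgb, chains of fibrinogen, had log2 fold changes of 0.82 and 0.80, and G6pc, the last enzyme of glucose release, 1.09 (edgeR adjusted p = 1 for each).

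Mitochondrially encoded genes rose with a median of 0.23, and heat shock proteins fell with -0.20 (camera adjusted p = 0.00733 for each; adjusted p = 0.447 and 0.628 with an estimated correlation). Without the library labelled Ctgf knockout replicate 2 they gave 0.0641 and 0.623, the heat shock median turning to 0.03. The mitochondrial list also gave 0.195 without Ctgf knockout replicate 1 and 0.0675 without Ctgf control replicate 1. In all, 7 lists rose and 12 fell of 46 in the Ctgf comparison, of which 0 passed with an estimated correlation and 0 with fry. Other splits of the same Ctgf libraries into pairs gave 21 and 22 lists by camera. Here too the number of lists does not set the labelled knockouts apart from other groupings. Sox9, Spp1 and Mki67 had log2 fold changes of -0.25, -0.42 and -1.10, and Alb and Afp 0.50 and 0.19, the last pair with a sign that turned without the library labelled Ctgf knockout replicate 2 (edgeR adjusted p = 1 for each). Cyp2e1, Ankrd1, Krt19 and Epcam had log2 fold changes of 0.09, -0.55, -0.43 and 0.08.

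The third comparison set the Yap1 effect against the Ctgf effect. The control groups differed too, with 178 genes higher and 155 lower in the Yap controls by edgeR's quasi-likelihood test (adjusted p under 0.05). A difference between the effects therefore cannot be told apart from a difference in the state of the controls. Neutrophil markers differed most among the lists, with a median difference in log2 fold change of 2.57, and 13 of 20 were higher over the list alone and 0 over all genes (camera adjusted p = 5.58e-20, adjusted p = 0.189 with an estimated correlation). Cholesterol synthesis and glycolysis and hypoxia differed by 1.16 and 1.05, with 13 and 5 members over the list alone (camera adjusted p = 1.59e-17 and 1e-13; adjusted p = 0.494 and 0.189 with an estimated correlation). Of single genes, Adm and Cd28 came nearest, with differences of 3.63 and 4.92 (edgeR adjusted p = 0.0618 and 0.0952). By edgeR's quasi-likelihood test 0 genes differed, with 1242 at an unadjusted p under 0.05, 0 by limma-voom, 166 by DESeq2, and 2 by edgeR without a low-count filter (Adm and Cd28). By edgeR more genes differed without Yap control replicate 1, which leaves the library with pancreatic transcripts as the only Yap control. More also differed without both Yap control replicate 2 and the library labelled Ctgf knockout replicate 2. In all, 14 lists differed upward and 8 downward by camera, with adjusted p = 0.189 to 0.749 with an estimated correlation, and fry passed 0. Through each left-out library 7 of the 22 passed.

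The genes called in both knockout comparisons numbered 0, against 0 from independent lists, because the Ctgf comparison made no call by edgeR. With DESeq2 there was 1, which must be among its Ctgf calls Lpin1, Ifi202b, Ndor1 and Ctrb1. The pancreas gene Ctrb1 stood at 5454 CPM in Yap control replicate 2, so this call may come from pancreatic transcripts. It is not read as an effect common to both knockouts. The comparisons share no control library.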

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

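The tests of pancreatic tissue, of carried-over reads, of intestinal or gastric tissue, of a label swap, of incomplete deletion, of pancreatic tissue as a source of the Ctgf difference and of the stellate cell share were chosen only after the result was seen. The tests of a Ctgf control under a wrong label, of Wwtr1 and of the other splits of the libraries were written down before their own outcome was seen. That of Wwtr1 was chosen once the Ctgf levels were known.

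Transcripts of the exocrine pancreas, a signal in a list that entered no test because the low-count filter left only 2 of its 17 genes, summed to 16731 CPM in Yap control replicate 2 and to 3.13 to 8.20 CPM in the other libraries. Pancreatic tissue in that sample fits, since 100% of the 15 genes with 3 or more counts in a library, from Cela1 at 107.8-fold upward, lay at least 100-fold above the highest other library (the remaining list members, Amy2a5 and Prss1, had 2 and 0 counts), and the islet genes summed to 47.3 CPM there. Reads carried over from another library of the series are excluded, because the highest sum elsewhere was 0.049% of this one. The 19 genes of intestine and stomach had a median log2 ratio of 2.19 to the highest other library, 11 of them at 4-fold or more. Stomach genes summed to 156.9 CPM in Yap control replicate 2 and to 0.17 to 2.47 CPM in the other libraries. Gkn1, Gkn2, Gkn3, Pgc and Tff1 had log2 ratios of 6.48 to 10, with Gkn3 at 111 CPM. The stomach genes Muc5ac and Atp4a, each at 0.41 CPM there, went the other way at -2.03 and -1.27. Atp4b and Gif, also on the stomach list, stood at 0 CPM in every library. The combined test of the 19 genes did not decide, and only the raised stomach genes go with gastric tissue in the sample. Whether intestinal tissue was there too cannot be told apart, because its genes went both ways, with Defa24 at 6.42 and Cdh17 at -0.121. No biological explanation was tested, because no group of the design accounts for pancreatic genes in a single control.

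The library labelled Ctgf knockout replicate 2 held Ctgf at 49.2 CPM, above both controls. A label swap with a Ctgf control of the series was judged by Ctgf alone, and the lower control held 3.59 times the level of Ctgf knockout replicate 1. This speaks against a swap only if every true knockout stands near that level, which incomplete deletion would not require. Whether this library is a Ctgf control under a wrong label cannot be told apart from a true knockout: 54.1% of 207 genes (112) that set replicate 1 apart from the controls moved the same way in it, which decides nothing, because both were measured against the same controls. Values that run as labelled in both libraries are Ifi202b at 0 counts, Cyr61 at 39.9 and 42.4 against 80.7 and 91.1 CPM, Tnf at 1.14 and 1.81 against 6.38 and 5.80 CPM, Retnlg at 3.94 and 3.85 against 9.95 and 13.2 CPM, and the mesothelial sum at 9.29 and 6.96 against 24 and 17.9 CPM, but all except Cyr61, a gene named beforehand, were picked after they were seen, from a comparison that includes this library, and Ifi202b may follow the strain. Incomplete deletion with induction in the remaining cells, the biological explanation, also cannot be told apart from these, because a level of 1.62 times the control mean in a table of gene counts holds no value specific to it.

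Ctgf stood higher in both Yap1 knockouts than in both Yap controls, with a log2 fold change of 2.31 (SE 0.718), although YAP is known to activate it. Pancreatic tissue in Yap control replicate 2 cannot be told apart as a part of this, because the log2 fold change without that library was 1.92 with an SE of 0.923 (edgeR adjusted p = 0.401), an error too wide for the limit set. A larger share of stellate cell RNA as the whole of it fell short of the limit set, since the 31 genes of the fibrosis and activated stellate cell list had a median of 0.21 (SD 0.712). That limit allowed Ctgf only its SE of 0.718, and 20 of the genes lay above 0 and 11 below. The test therefore does not exclude such a share. Higher expression of the related factor TAZ, the biological explanation, cannot be told apart, because the log2 fold change of Wwtr1, a gene picked once the Ctgf levels were known, was 0.40 with an SE of 0.29.

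Each line has 3 splits of its 4 libraries into pairs, which are too few for a test by permutation. In the Yap line the real split gave 4 genes and the highest other 0, so 1 split, the real split itself, reached that number. At an unadjusted p under 0.05 the real split gave 1928 genes and the others 1034 and 272. For lists the real split gave 23 and the others 22 and 24, and 2 splits, the real split among them, reached that number. In the Ctgf line the real split gave 0 genes and the highest other 0, and for lists 19 and the highest other 22. All 3 splits, the real split among them, thus reached each number. In both lines about as many lists passed camera whichever pair was set apart. The number of lists therefore does not show an effect of deletion.

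The Yap1 and the Ctgf effect differed by camera in 22 lists, given here as the median difference in log2 fold change. Upward these were neutrophil markers at 2.57, the CCN family at 1.41, cholesterol synthesis at 1.16, glycolysis and hypoxia genes at 1.05, erythroid genes at 1.00, immediate early genes at 0.74, fibrosis and activated stellate cell genes at 0.70 and the YAP/TAZ target signature at 0.58. Further upward ones were the TGF-beta response at 0.53, integrins and adhesion at 0.49, growth factors and receptors of regeneration at 0.46, Kupffer cell markers at 0.41, Hippo pathway components at 0.36 and inflammatory cytokines and chemokines at 0.23. Downward these were xenobiotic metabolism at -1.21, pericentral hepatocyte genes at -0.71, bile acid synthesis and transport at -0.55, PPAR-alpha and fatty acid oxidation at -0.47, hepatocyte core genes at -0.46, cytosolic ribosomal proteins at -0.44, sinusoidal endothelial markers at -0.41 and fatty acid and triglyceride synthesis at -0.38. Without Yap control replicate 2 the medians were 0.20 for pericentral genes, 0.10 for ribosomal proteins, 0.0784 for hepatocyte core genes and -0.20 for xenobiotic metabolism (camera adjusted p = 0.793, 0.727, 0.75 and 0.905), and bile acid and PPAR-alpha genes gave 0.481 and 0.693. Without both that library and the one labelled Ctgf knockout replicate 2 the median of xenobiotic metabolism was 0.51 (0.11), and hepatocyte core genes passed the other way at 0.38 (0.00107). With an estimated correlation the adjusted p of these lists was 0.189 to 0.749.

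Of these 22 lists, 7 passed through each left-out library: neutrophil markers, cholesterol synthesis, glycolysis and hypoxia, immediate early genes, fibrosis, the YAP/TAZ signature and integrins. In this order, the medians of the first 4 ran from 2.16 to 3.66, 0.87 to 1.83, 0.74 to 1.33 and 0.63 to 1.17. Those of fibrosis, the YAP/TAZ signature and integrins ran from 0.48 to 1.12, 0.34 to 1.13 and 0.33 to 1.05. Kupffer cell markers did not pass with RLE factors, with the stricter filter or without any of 5 libraries, with medians down to -0.0261. Hippo pathway components did not pass without any of 4 libraries, with medians down to -0.0154, and cytokines and chemokines not with the stricter filter or without Yap control replicate 1 or Ctgf knockout replicate 1, where the median was -0.0853. Erythroid genes and the CCN family gave camera adjusted p of 0.186 and 0.285 without Yap control replicate 1, and the CCN family 0.0577 without Yap1 knockout replicate 1. The TGF-beta response gave 0.114 without Yap control replicate 2, and it and the growth factors gave 0.0932 and 0.0924 without Ctgf knockout replicate 1. Sinusoidal markers gave 0.403 without Yap control replicate 1 and 0.167 without Ctgf control replicate 1. Fatty acid and triglyceride synthesis gave 0.0616 without Yap1 knockout replicate 1 and 0.138 without the library labelled Ctgf knockout replicate 2. Hepatocyte core genes gave 0.0607 without Ctgf control replicate 2 and 0.816 without the library labelled Ctgf knockout replicate 2, and ribosomal proteins 0.0588 without Ctgf knockout replicate 1.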

How the results depend on the processing

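Of 2980 gene results under other settings 2740 kept their direction and side of the threshold, 22 were weaker, 179 stronger and 39 reversed. Only 4 genes had passed in the main fit, all in the Yap1 comparison. The 22 weaker results are all lost calls of these 4 genes, and most kept results are genes that passed in neither fit. The kept share therefore does not measure how stable the calls are. Of 894 list results 660 were kept, 211 weaker and 23 reversed. Groups of 2 limit every call, and a lone library left in a group is assumed to vary like the other groups. DESeq2 gave 277 genes higher and 281 lower for Yap1, 1 and 3 for Ctgf, 166 for the difference, 1 shared call and Yap1 at -1.53 (adjusted p = 6.01e-08). Limma-voom gave 1 gene lower for Ctgf. A minimum change of 2-fold left every count of calls as it was. Without a low-count filter there were 24 higher and 13 lower for Yap1, 2 for the difference, and Yap1 at -1.53 (adjusted p = 0.0458). The Yap libraries alone gave 0 higher and 0 lower. With an estimated correlation 0 lists passed in each comparison, and with fry 2 for Yap1, 0 for Ctgf and 0 for the difference. The cause of these shifts was not tested.

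The titles of the Yap controls each name a numbered knockout, but what ties them is not stated and the numbers in the column names do not settle it, so the replicate numbers were not used as a pairing; the correlations of deviations were 0.0716 in the Yap line and 0.0679 in the Ctgf line. With the replicate number as a block 12 genes were higher and 7 lower for Yap1, and 0 differed for Ctgf and for the difference. The lists past the camera test were then 25 for Yap1, 19 for Ctgf and 24 for the difference. With the replicate block the mitochondrially encoded genes in the Yap1 knockout comparison did not pass (camera adjusted p = 0.0558).

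With single libraries left out, the Yap1 comparison gave 0 to 1788 genes higher, 0 to 1940 lower and 20 to 28 lists, the Ctgf comparison 17 to 24 lists, and the difference 0 to 2092 genes and 20 to 25 lists. The highest gene numbers came without Yap control replicate 1, which leaves the library with pancreatic transcripts as the only Yap control. The log2 fold change of Yap1 ran from -1.75 to -1.29 and that of Ctgf in its own comparison from -1.92 to 0.71. In the Yap1 comparison the direction of a gene or of a list test turned within these ranges: Afp -0.23 to 2.91, Alb -0.62 to 0.20, Col1a1 -0.23 to 0.18, Cyp2e1 -1.45 to 1.33, Epcam -2.76 to 0.49, Krt19 -3.60 to 0.93, Mki67 -1.12 to 0.54, Rpl13 -1.13 to 0.0137, Rps15 -1.22 to 0.0309, Spp1 -1.33 to 0.76, ribosomal proteins -0.69 to 0.14 and xenobiotic metabolism -1.14 to 0.52. In the Ctgf comparison they were Afp -0.14 to 0.47, Alb -0.11 to 0.94, Cyp2f2 -0.0621 to 1.82, Epcam -0.26 to 0.35, Hsp90aa1 -0.68 to 0.0695, Nov -1.58 to 0.0932, Slco1a1 -0.51 to 1.89, Wisp1 -0.53 to 0.19, Yap1 -0.0105 to 0.0584, heat shock proteins -0.61 to 0.0282, hepatocyte core genes -0.12 to 0.56, macrophage markers -1.26 to 0.0901, periportal genes -0.16 to 0.63 and xenobiotic metabolism -0.12 to 0.80. In the difference they were ribosomal proteins -0.82 to 0.10, hepatocyte core genes -0.92 to 0.0784, cytokines and chemokines -0.0853 to 0.77, pericentral genes -1.38 to 0.20 and PPAR-alpha genes -0.96 to -0.0474, where the test and not the median turned. The median but not the test turned for acute phase proteins (-0.12 to 1.14) and bile acid genes (-0.54 to 0.13) in the Yap1 comparison, for male-biased genes (-0.0191 to 0.66), fatty acid and triglyceride synthesis (-0.0166 to 0.36) and the CCN family (-1.01 to 0.0296) in the Ctgf comparison, and for Kupffer cell markers (-0.0261 to 0.81) and Hippo components (-0.0154 to 0.96) in the difference. The cause was not tested.

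Without both Yap control replicate 2 and the library labelled Ctgf knockout replicate 2, a setting chosen after seeing the data, 530 genes were higher and 408 lower for Yap1, 143 differed, and Yap1 stood at -1.75 (adjusted p = 0.00635). Reversed in the Yap1 comparison were Alb 0.19, Cyp2e1 1.33, Epcam 0.49, Krt19 0.93, Rpl13 0.0126, Rps15 0.0299, Spp1 0.76, ribosomal proteins 0.14 and xenobiotic metabolism 0.52. Reversed in the Ctgf comparison were Afp -0.14, Alb -0.11, Cyp2f2 -0.0623, Epcam -0.25, Hsp90aa1 0.0699, Nov 0.023, Slco1a1 -0.50, Wisp1 0.19, hepatocyte core genes -0.12, xenobiotic metabolism -0.0763, periportal genes -0.16 and heat shock proteins 0.0286. Reversed in the difference were xenobiotic metabolism 0.51, PPAR-alpha genes 0.14, pericentral genes 0.36, ribosomal proteins 0.11 and hepatocyte core genes 0.38. Both left-out libraries were picked for standing apart, and the cause was not tested further.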

Other observations

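The test of mesothelial genes was chosen only after the result was seen, as were the genes named in this part.

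Genes of glucose and amino acid handling in the Yap1 comparison moved both ways. Fbp1, a key enzyme of gluconeogenesis, had a log2 fold change of 2.02 (SE 0.281), Aass, which degrades lysine, 2.13 (SE 0.404), and Tat, which degrades tyrosine, 1.59 (SE 0.346), with edgeR adjusted p of 0.0557, 0.12 and 0.153. Hgd and Prodh, of tyrosine and proline breakdown, had -1.77 and -1.72. In that list 7 members were higher and 3 lower when adjusted over the list alone, and its camera adjusted p was 0.0615. Hmox1, the heme oxygenase induced by oxidative stress, had a log2 fold change of 1.94 (SE 0.295) and Ephx1, an epoxide hydrolase, -2.03 (SE 0.37), while the NRF2 target list that holds them had a median of -0.14 (camera adjusted p = 0.487).

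Set against the Ctgf controls, the Yap controls had 178 genes higher and 155 lower by edgeR's quasi-likelihood test. They held more transcript of matrix-producing cells. The log2 differences were 4.52 (SE 0.285) for Acta2, 3.23 (SE 0.276) for Col1a1 and 2.53 (SE 0.27) for Des, with edgeR adjusted p of 0.00205, 0.0104 and 0.021. The fibrosis and activated stellate cell list had a median of 2.10 (camera adjusted p = 1.12e-30, adjusted p = 0.372 with an estimated correlation) and mitosis genes 2.86 (camera adjusted p = 8.29e-31, adjusted p = 0.773 with an estimated correlation). Heat shock proteins stood lower, with a median of -1.20 (camera adjusted p = 1.53e-08, adjusted p = 0.773 with an estimated correlation). This comparison lay outside the design, was chosen after seeing the data, and joins the mouse line, the virus and any difference in handling.

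Among the lowest p-values of the Ctgf comparison stood Msln, Muc16 and Lrrn4, genes of the mesothelium that covers the liver, with log2 fold changes of -1.91, -2.53 and -1.80. As a hypothesis, the samples labelled Ctgf knockout held fewer mesothelial cells. This fits, since the other mesothelial markers had a median of -1.21 with 9 of 9 below 0. They were read in the same libraries as the genes first seen and mark the same cells, so they are not independent support. The 12 markers summed to 24 and 17.9 CPM in the controls, to 9.29 CPM in Ctgf knockout replicate 1 and to 6.96 CPM in the library labelled Ctgf knockout replicate 2, whose Ctgf level goes against its label. The share of liver surface in the piece of tissue taken was not tested.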
